A study of Mus musculus with 2 samples.

How the data were processed

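Buccal epithelium of 12-week-old C57BL/6 female mice was pooled from 10 animals, sorted for cells with much CD104 (the β4-integrin chain, gene Itgb4) on their surface, and loaded on the 10x Chromium platform. Per the labels, 1 suspension was divided into 2 technical replicates, called library 1 and library 2 here, so there is 1 independent sample. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode. The submitters' processing notes name Cell Ranger (version not given in the sources used here) and the mouse build mm10. The cell-calling filter and the gene annotation were not given. The files hold 27998 genes, of which 27645 (98.7%) were matched by Ensembl identifier to GENCODE M21 on GRCm38 (the same assembly as mm10), the source of all coordinates. All 267 named genes were matched.

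Library 1 held 7215 barcodes and 67962712 UMIs, with a median of 7485 UMIs and 2400 genes per barcode. Library 2 held 9076 barcodes and 73935792 UMIs, with medians of 6459 and 2204. The lowest barcode had 3362 UMIs in library 1 and 3149 in library 2, so barcodes had been filtered before deposit and empty droplets were not available for an estimate of free RNA. The smallest classes held 8 to 25 cells per library, which bounds the precision of any share measured in them. A gene had to reach 20 CPM to be compared.

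Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were sought with Scrublet (scanpy 1.11.5) in each library. It marked 1 barcode per library (0.0139% and 0.011%), under the 0.5% at which its calls were to be used, so no doublets were removed. UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen per library and merged by rank, without mitochondrial genes and without any gene of the 24 readout lists. This kept list genes from forming the clusters directly. Genes outside the lists that vary with them were not kept out. List differences between clusters are therefore not independent of how the clusters formed. Standardised values gave 30 principal components, and each cell's 15 nearest neighbours gave a graph of shared neighbours (Jaccard index of at least 0.0667). Leiden clustering used resolution 0.8, 10 iterations and seed 1, and the libraries were not integrated. Software was Python 3.11.15 with anndata 0.12.19, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

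Clusters were named from 17 marker lists, and "-like" marks that a name rests on transcripts. A name outside keratinocytes needed 3 markers at 100 CPM or more and 8-fold above the remaining cells. A phase name (S or G2/M) needed a median log2 of at least 1.0 over all cells. Phase names were given first, so a cluster with a phase name can also meet the basal markers. A basal or differentiating name needed a median log2 of at least 0.5 and a lead of 1.0 over the other side. A name was withheld where more of the 10 leading genes (at least 50 CPM, 5 CPM added to both sides) were markers of another list than of its own. These naming thresholds were set after the data were seen. The gene lists, the filters, the clustering settings, the comparisons, the size rule, the rule for named genes and the alternatives described as planned were chosen before the data were examined.

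Levels are counts scaled to 1000000 UMIs (CPM) after summing over the cells of a class in each library. Class means weight the libraries equally. Because the libraries are technical splits of 1 suspension, no significance test was run and cells were not treated as replicates. A gene was called higher or lower by a size rule: at least 1.5-fold (0.58 on the log2 scale) in the same direction in both libraries, with a mean of at least 20 CPM. Class comparisons counted genes used neither for clustering nor in a marker list, nor mitochondrial. A count of 0 was set to 3. Each readout list was described by its members past the rule, its median log2 ratio, and the percentile of that median among 10000 random lists matched on level in 20 bins. In the comparison of basal clusters a list counted as apart with at least 3 measured genes and a median past 1.5-fold in both libraries. Intervals are 95% exact binomial for shares and exact conditional binomial for ratios, and cover counting error only. Between the libraries, levels were compared across genes, with a chi-square against multinomial sampling and with the barcodes found in both.

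Genes named in the text are, for each class comparison, the 12 readout-list genes highest and the 12 lowest by the smaller of the library ratios, with Itgb4, Itga6 and Col17a1 always, and up to 4 examples per list. For the libraries they are the 5 genes furthest apart each way, for purity the 3 most abundant markers of each list that named a cluster with Itgb4, Krt5, Krt14 and Trp63, and for basal clusters the 3 readout genes furthest apart. Genes that led a cluster, the remaining genes past the rule between libraries, and every gene given for comparisons of single clusters were chosen after their values were seen.

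The calling rule was tested on simulated data with the depths of these classes. This covered 5204 genes for the differentiating-like, 5210 for the cycling-like and 5119 for the library comparison. Counts were drawn from a shared profile with counting noise only, without variation between cells or libraries. The values below therefore measure counting error alone, not the error of the rule in these data. Genes set 1.5-fold apart lay on the cutoff itself. In the differentiating-like comparison 0 of 5022 unaltered genes were called, and 0 of 48 genes set 1.25-fold apart, 18 of 48 at 1.5-fold, 45 of 45 at 2-fold and 41 of 41 at 4-fold were recovered. In the cycling-like comparison the corresponding values were 0 of 5028, 0 of 49, 10 of 50, 43 of 43 and 40 of 40. Between simulated libraries without a difference, 0 of 5119 genes were called.

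Alternatives were a looser and a stricter cell filter (200 genes and 20% mitochondrial UMIs, 1000 genes and 5%), resolutions 0.4 and 1.2, 1000 and 4000 variable genes, readout genes allowed in clustering, classes from per-cell phase calls and marker scores, median-of-ratios scaling, level floors of 5 and 50 CPM, a 2-fold rule, cells thinned to 3000 UMIs, and each replicate left out. Doublet scores and a wider basal-like class were added after the data were seen.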

Results

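Stratified oral epithelium is renewed from its basal layer, whose cells hold to the basement membrane through hemidesmosomes built on the α6β4-integrin. Cells sorted for that integrin were profiled one by one to look for sub-populations within the layer. Of 16291 barcodes, 15470 were kept (6907 in library 1 and 8563 in library 2), and 821 were left out for mitochondrial UMIs.

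The libraries held much the same transcripts. Of 5120 genes with a mean level of at least 20 CPM (UMIs of a gene in every 1000000 UMIs), 8 lay past 1.5-fold, 7 of them higher in library 2. Of these 7, the antigen-presentation genes Cd74 (178 against 73.7 CPM, log2 1.27), H2-Ab1 (1.24), H2-Aa (1.23) and H2-Eb1 (1.16) are the transcripts of the Langerhans-like cells, of which library 2 held 25 and library 1 held 8. Cnfn (0.63), Lor (0.84) and Crct1 (1.06), which encode proteins of the cornified envelope or its gene cluster, were the others. In library 1, AY036118 was higher (569 against 298, log2 -0.93), followed within 1.5-fold by mt-Nd3 (-0.55), Rps12-ps3 (-0.55), Gm26917 (-0.54) and Gm10073 (-0.54). Levels correlated across genes with Pearson's r of 0.997 and Spearman's rho of 0.994, where genes are not independent replicates. Counts summed over cells still differed between the libraries by more than multinomial counting noise. The chi-square per degree of freedom was 18.8 over 17956 genes in all kept cells and 4.25 over 15264 genes within the largest cluster. It treats each UMI as an independent draw, although UMIs come grouped in cells, and no random split of the cells was run beside it. These values therefore do not measure a library effect alone. The 104 barcodes present in both libraries were no more alike (median cosine similarity 0.667) than random pairs across libraries (0.672).

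By their markers, nearly all kept cells were keratinocytes. Clusters named from markers of other cells held 1.43% of library 1 (99 of 6907 cells, interval 1.17 to 1.74) and 1.23% of library 2 (105 of 8563, 1.004 to 1.48). The most frequent were glandular-like cells (1.09% and 0.818%). They carried the simple-epithelium keratins Krt7 (1288 CPM against 2.62 in basal-like cells) and Krt18 (313 against 0.755). They also held the secreted protein gene Wfdc2 (1040 against 74.5) and Itgb4 at 176 CPM. Basal genes were present in them as well, with Krt14 at 11789 CPM (9935 in basal-like cells), Krt5 at 3205 (3566) and Trp63 at 336 (518). Langerhans-like cells (0.116% and 0.292%) carried the class II genes Cd74 (56018 CPM against 6.82 in basal-like cells), H2-Ab1 (22854 against 5.10) and H2-Aa (16399 against 2.38). T/NK-like cells (0.232% and 0.117%) carried the cytotoxic granule gene Nkg7 (2348 against 0.489), Cd52 (1505 against 1.40) and Cd7 (519 against 0.347). No T/NK-like cluster was named when either library was clustered alone. No cluster earned a fibroblast, endothelial, pericyte or smooth muscle, Schwann, melanocyte, mast, Merkel or taste, hair follicle or sebaceous, skeletal muscle or erythroid name. The highest level of any marker on those lists was Dcn on the fibroblast list, at 6094 CPM in cluster 11. It was followed by Krt18 (Merkel or taste, 313 in the glandular-like cluster), Cst6 (hair follicle or sebaceous, 273 in cluster 5), Mbp (Schwann, 43.7), Acta2 (pericyte or smooth muscle, 25.9), Hba-a1 (erythroid, 22.6), Kit (mast and melanocyte, 13.9), Ckm (skeletal muscle, 10.1) and Ptprb (endothelial, 7.203).

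Keratinocytes divided into basal-like, cycling-like and differentiating-like clusters of similar total size, with a remainder. Basal-like clusters held 24.9% of keratinocytes in library 1 (interval 23.9 to 26.0) and 22.0% in library 2 (21.1 to 22.9). Differentiating-like clusters held 21.3% (20.3 to 22.3) and 24.0% (23.1 to 24.9). Cycling-like clusters held 27.5% (26.4 to 28.6) and 28.0% (27.1 to 29.0). Of the cycling-like cells, S-like clusters made up 7.31% and 6.83% of keratinocytes and G2/M-like clusters 20.2% and 21.2%. The remaining 26.3% and 26.0% lay in 4 clusters left without a name, of which clusters 8 and 11 met the basal markers and clusters 2 and 10 met neither side. The classes are not exclusive states, because phase names were given first. Cycling-like clusters 3 and 7 also met the basal thresholds (median log2 of the basal markers 0.61 and 0.51), whereas cycling-like cluster 6 did not (-0.28). The cycling-like share differed between the libraries by less than counting error, whereas the intervals of the basal-like share and of the differentiating-like share did not overlap between libraries.

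Itgb4, the gene of the sorted antigen (ENSMUSG00000020758, GRCm38 chromosome 11, 115974709 to 116008412), differed about as much between these classes as the basal keratins did. It stood at 133 CPM in basal-like cells (144 and 122 in the libraries), 92.8 in cycling-like cells and 11.5 in differentiating-like cells (10.99 and 12.05). Krt14, the basal type I keratin (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548), went from 9935 in basal-like to 984 in differentiating-like cells. Its partner Krt5 went from 3566 to 502, and Trp63, a transcription factor of the basal layer, from 518 to 130. These last 3 genes named the classes, so their difference is built in, whereas Itgb4 took no part in clustering. Genes that vary with Itgb4 were not kept out, so its difference is not independent of the classes either. With every cell thinned to 3000 UMIs, 35.4% and 30.2% of basal-like cells had an Itgb4 UMI, against 3.66% and 3.35% of differentiating-like cells. Langerhans-like cells, thinned alike, had one in 0 of 8 cells in library 1 and in 16.0% of 25 cells in library 2. Their intervals (0 to 36.9% and 4.54% to 36.1%) are wide enough to hold the basal-like shares as well. This reference is therefore too small to tell whether the share in differentiating-like cells came from free RNA. The plot of 4 genes by cluster shows the gradient.

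**Figure D1:**
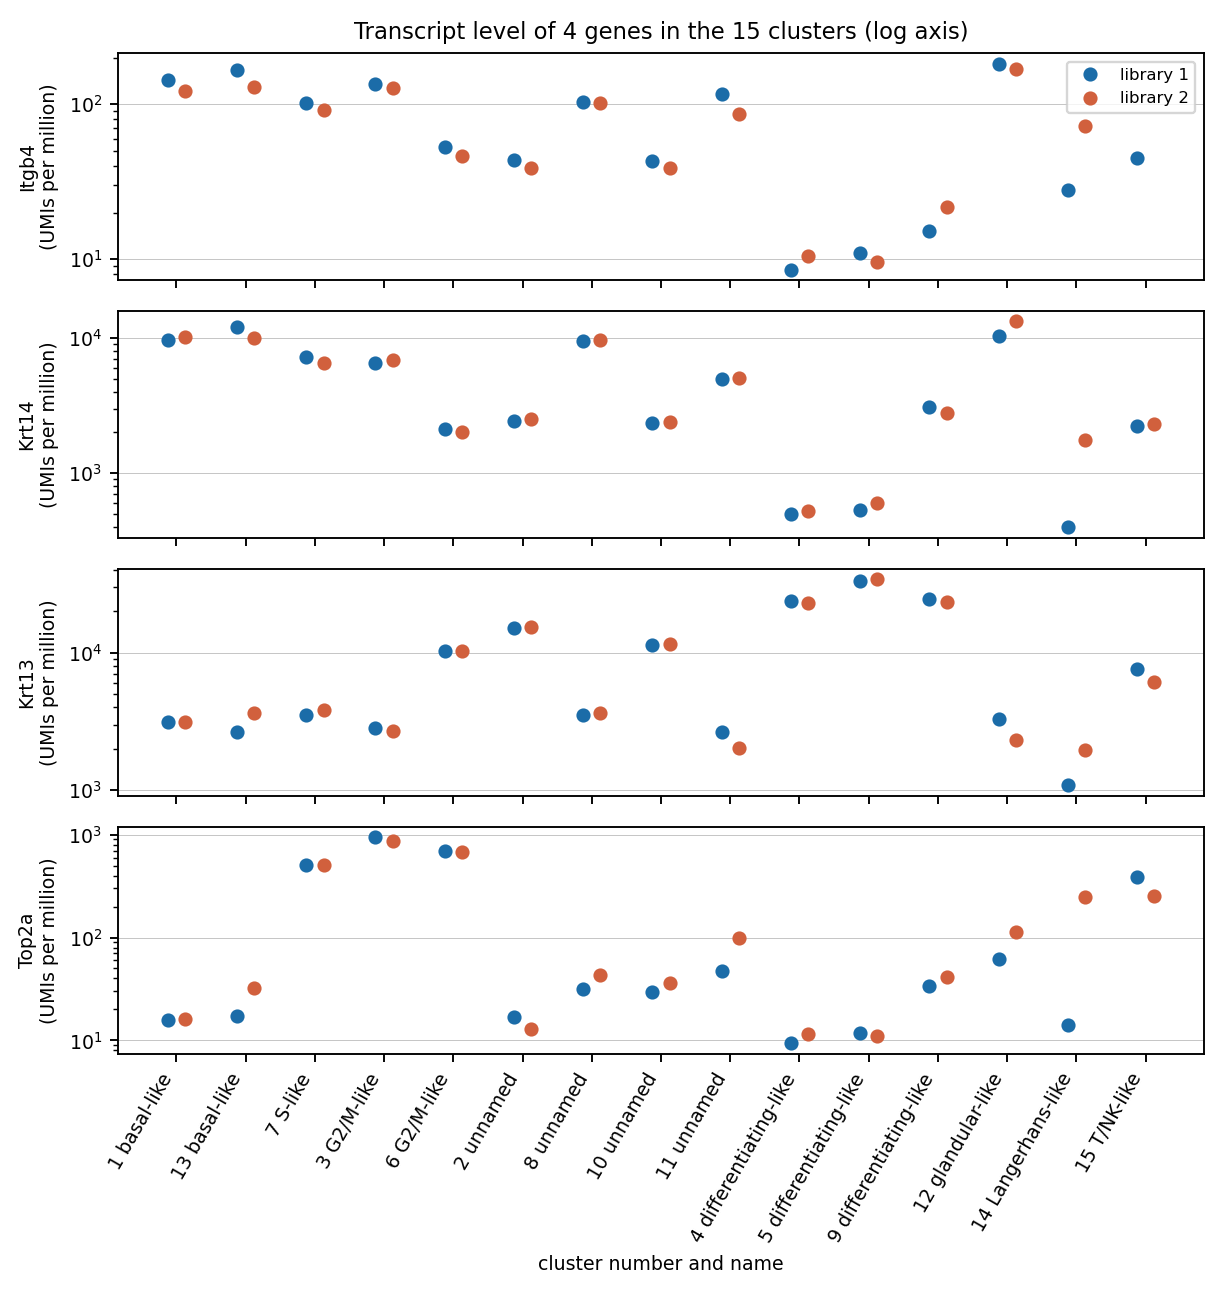
CPM (log axis, UMIs in every 1000000) of Itgb4, Krt14, Krt13 and Top2a in each of 15 clusters, with 1 point per library; levels of 0 are not drawn. Itgb4 was 133 CPM in cluster 1 and 10.2 in cluster 5, and Krt13 was 3130 and 33682.

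Differentiating-like cells had low transcript levels for the machinery that anchors a cell to the basement membrane and high levels for that which builds the barrier. Of 9 measured genes of hemidesmosomes and basement membrane, 8 were lower by the size rule and 0 higher (median log2 -3.36). They included the β3 laminin chain gene Lamb3 (3.53 against 71.3 CPM, log2 -4.34; ENSMUSG00000026639, chromosome 1, 193207699 to 193343878). The collagen XVII gene was among them (Col17a1, 25.2 against 376, log2 -3.99 and -3.80 in the libraries; ENSMUSG00000025064, chromosome 19, 47646344 to 47692094). So were Itgb4 (-3.71 and -3.34) and its partner Itga6 (35.9 against 369, log2 -3.50 and -3.23; ENSMUSG00000027111, chromosome 2, 71745616 to 71858416). Genes related to the cornified envelope but outside its list, such as Crct1, were not kept out of clustering. All 14 measured genes of the list were higher (median 3.62). Among them were the cross-linked precursors Sprr1b (51.8 against 1.53, log2 5.06) and Sprr3 (49.6 against 1.57), the envelope protein gene Cnfn (303 against 13.0, log2 4.53) and the long-chain fatty acid elongase Elovl4 (4.72). Desmosomes, which join cells to one another, were higher in 7 of 10 genes and lower in 0 (median 1.16), with the suprabasal cadherins Dsg1a (183 against 13.5, log2 3.77) and Dsg1b (3.25) in front. The list of wound-associated keratins and alarmins was higher in 4 of 4 measured genes over the class (median 4.16). Its clusters were not alike. In cluster 9, 6 of 7 measured genes were higher (median 6.49). There were 2 higher and 1 lower of 4 in cluster 5 (3.02), and 2 higher and 1 lower of 3 in cluster 4 (1.86). These medians rest on different genes: only 4 of the list are keratins, so the 7 in cluster 9 include alarmins. Krt17, at 0.90 over the class, was at -2.23 in cluster 4 and -1.49 in cluster 5. In front were Krt6b (495 against 11.6, log2 5.55 and 5.29; ENSMUSG00000023041, chromosome 15, 101676023 to 101680287), Krt16 (190 against 7.21, log2 4.71 and 4.73) and Krt6a (3.60). Within the class, Krt16 stood at 875 CPM in cluster 9 and at 32.1 in the other differentiating-like clusters. Its sign turned to -0.57 when classes were taken from per-cell marker scores. Cholesterol synthesis was higher in 9 of 10 genes and lower in 0 (median 2.71). Examples were the squalene epoxidase Sqle (49.0 against 2.66, log2 4.23) and the prenyl synthase Fdps (278 against 24.4, log2 3.51; ENSMUSG00000059743, chromosome 3, 89093588 to 89101959).

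Signalling genes of the basal layer went the other way. The Wnt list was lower in 6 of 8 genes (median -1.23). Its ligand Wnt10a was among the lowest of the named genes (7.69 against 170 CPM, log2 -4.54 and -4.39, counting interval -4.61 to -4.30; ENSMUSG00000026167, chromosome 1, 74791516 to 74804179). The secreted Wnt modulators Dkk3 (-4.32) and Sfrp1 (-3.42) were lower as well. The TGF-β and BMP list was lower in 6 of 7 (median -1.24), with Tgfbr2 (-3.81) and Tgfbi (-3.58). The G1 cyclin Ccnd2 was at 63.0 against 962 CPM (log2 -3.93; ENSMUSG00000000184, chromosome 6, 127125162 to 127152193), whereas the cell cycle inhibitor Cdkn1a was at 417 against 41.9 (log2 3.32). Their list of cyclins and inhibitors went both ways (2 higher, 5 lower of 11, median -0.11). Epithelial transcription factors also went both ways (4 higher, 4 lower of 18, median -0.03). The higher ones were the differentiation regulators Zfp750 (3.56), Grhl1 (3.32), Grhl3 (2.86) and Ovol1 (1.88). Candidate stem cell markers were lower in 4 of 8 and higher in 2 (median -0.64, and 0.01 among genes of at least 50 CPM). The glutamate transporter Slc1a3 was at -3.37, Igfbp5 at -2.04 and Ly6d at 2.83. The Notch list (median 0.13) held Nrarp (2.79) and Hes1 (388 against 194 CPM) as higher and Notch1 (-0.95) as lower of 5. By cluster it was at 1.33 in cluster 4 (4 higher, 1 lower of 7), -0.28 in cluster 5 and 0.19 in cluster 9.

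The other lists moved less over the class, or on few genes. Tight and adherens junction genes were higher in 4 of 7, with Pvrl4 at 3.61 and Cdh1 at 0.88, but their median of 0.62 lay under the size rule in 11 alternatives (0.29 to 0.58). Single measured genes stood for the Hedgehog list (Smo, -1.35) and the YAP list (Ajuba, -2.30), and 2 for the EGF receptor list (Egfr -1.07, Erbb2 0.79). Clock genes were lower in 2 of 3 (Arntl -1.83, Clock -0.80) and higher in 1 (Bhlhe40, 0.96). Mixed lists were immediate early genes (3 higher, 2 lower of 11, median 0.11, with Klf4 1.82 and Btg2 -1.22) and heat shock (2 and 4 of 12, -0.19, with Hspb1 1.62 and Dnaja1 -1.41). Others were interferon response (2 and 1 of 9, 0.04; Bst2 2.05, Ifitm3 -1.74), p53 targets (1 and 1 of 5, 0.25; Ccng1 -0.76) and glycolysis (1 and 2 of 12, 0.04; Pgam1 0.67, Pfkp -1.16). The unfolded protein response was higher in 3 of 11 (0.29; Xbp1 1.18, Sdf2l1 1.08), while nuclear genes of oxidative phosphorylation (1 higher of 72, 0.08; Uqcrq 0.76) and of the ribosome (1 lower of 80, -0.27; Rps27 -0.67) lay within the size rule. Some of these medians hid differences between clusters. Heat shock was at -0.82 in cluster 4 (1 higher, 6 lower of 11, where the median of all genes was -0.27) and 0.17 in cluster 5. Interferon response was at 1.76 in cluster 9 (12 higher of 13), -0.43 in cluster 4 and -0.46 in cluster 5. The unfolded protein response was at 0.67 in cluster 9 and -0.24 in cluster 4.

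In this comparison of 3477 differentiating-like with 3555 basal-like cells, 398 genes were higher and 851 lower of 4279. The split depends on scaling, because the median of all compared genes was -0.24 on the log2 scale. With that shift removed by median-of-ratios scaling, 668 were higher and 429 lower. List medians relative to it were -3.12 for hemidesmosomes, 3.87 for the cornified envelope, 4.41 for wound keratins, 2.96 for cholesterol synthesis, 1.40 for desmosomes, -1.01 for Wnt, -0.996 for TGF-β and BMP, and -0.02 for ribosomal proteins. Relative to it, the stem cell list (-0.39) and the clock list (-0.56) lay within the size rule, and the medians of heat shock (0.06), cyclins and inhibitors (0.14), transcription factors (0.26) and EGF receptor genes (0.10) were above 0. Among random lists matched on level, the class medians lay at percentile 0 for hemidesmosomes, 0.18 for Wnt, 0.225 for TGF-β and BMP, 0.27 for ribosomal proteins, 99.5 for tight and adherens junctions, and above 99.9 for desmosomes, cornified envelope, wound keratins and cholesterol synthesis. The deposited counts were used as given for near-identical gene pairs (Krt6a and Krt6b, Dsg1a and Dsg1b), between which reads can be shared.

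**Figure D2:**
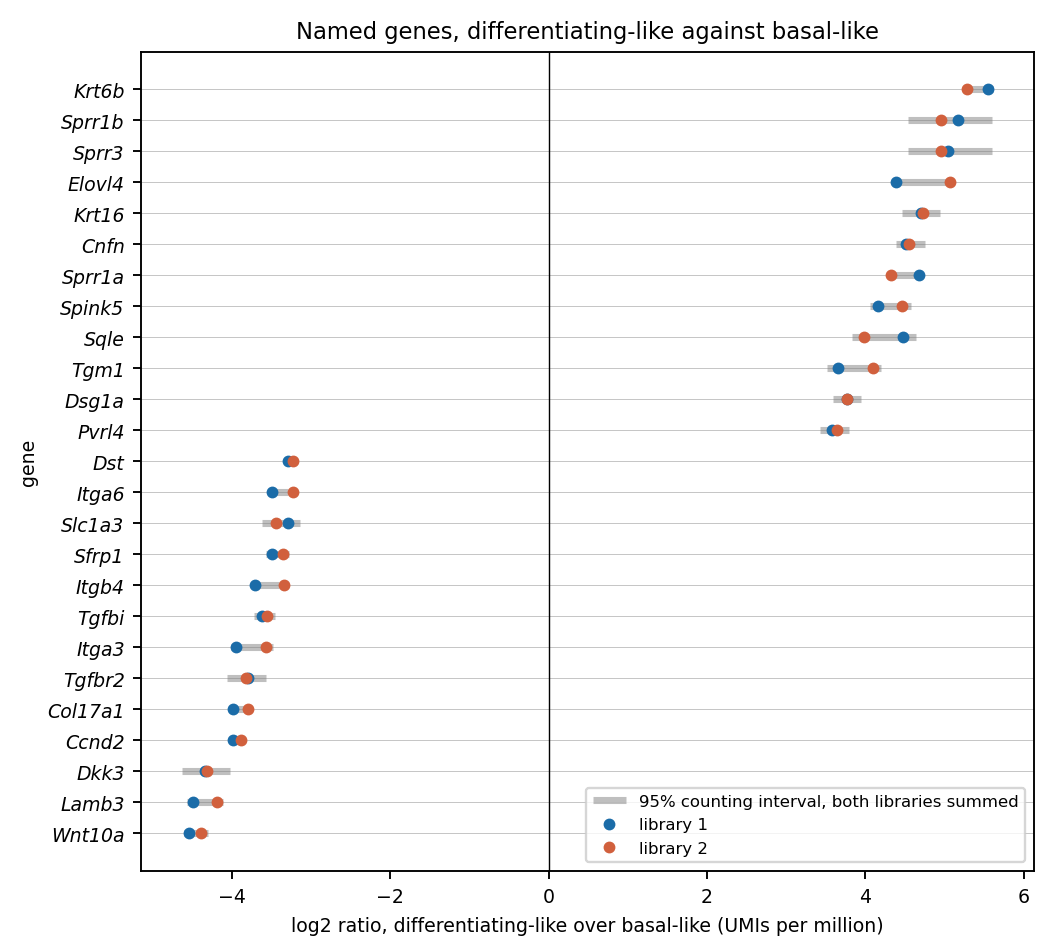
Log2 ratio of CPM, differentiating-like over basal-like, for the named genes, with 1 point per library and a bar for the 95% counting interval of both libraries summed. The genes run from Krt6b (5.42) to Wnt10a (-4.47), and the points of each gene lie on the same side of 0.

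Pooled over the class, cycling-like cells resembled basal-like cells in most lists, but their clusters were not alike. Against basal-like cells, G2/M-like cluster 6 had 37 readout genes higher and 34 lower of 317. In G2/M-like cluster 3 these were 12 and 14 of 318, and in S-like cells 19 and 21 of 315. Of the genes counted in class comparisons, 402 were higher and 217 lower of 4548 in cluster 6. In cluster 3, 345 were higher and 108 lower of 4620. Anchoring genes differed by cluster as well. Hemidesmosome genes were lower in 7 of 9 and higher in 0 over the class (median log2 -0.72). Against the same basal-like cells, they were lower in 8 of 9 in G2/M-like cluster 6 (-1.70) and in 5 of 10 in S-like cells (-0.68), but in 1 of 10 in the larger G2/M-like cluster 3 (-0.34). Median Krt4 and Krt13 UMIs per cell, given below, argue against doublets with differentiating-like cells as most of cluster 6, but do not exclude them in a part of it. The test written for such doublets, also given below, could not decide. Over the class, Itga6 was at -0.95 and -0.83, Col17a1 at -0.70 and -0.73 (-0.53, within the size rule, with cells thinned), Lamb3 at -1.05 (-0.54 without replicate 1), and Itgb4 at -0.57 and -0.46, within the rule. Ccnd2 was at 244 against 962 CPM (log2 -1.95 and -2.01). The INK4 inhibitor Cdkn2c (206 against 37.2, log2 2.43 and 2.51, counting interval 2.37 to 2.58; ENSMUSG00000028551, chromosome 4, 109660876 to 109667189), the pocket proteins Rbl1 (1.57) and Rb1 (1.14) and the kinase Cdk2 (1.09) were higher. Their list had 6 genes higher and 1 lower of 14 (median 0.29). Cholesterol synthesis was higher in 4 of 7 and lower in 0 (median 0.83, and 0.30 among genes of at least 50 CPM), with Idi1 (1.75), Fdft1 (1.64), Fdps (1.26) and Pmvk (0.83). It was higher in 5 of 8 genes in cluster 6 (1.42), 3 of 7 in S-like cells (0.59) and 1 of 6 in cluster 3 (0.11). Krt6a (1.65) was 1 of only 2 measured wound genes, whose median of 0.90 became -0.07 with cells thinned. Wnt genes were lower in 3 of 7 (median -0.57; Wnt10a -1.12, Dkk3 -1.07, Sfrp1 -0.78) and TGF-β and BMP genes in 2 of 9 (-0.34; Tgfbi -1.18, Tgfbr2 -0.73). These medians were -0.97 and -0.96 in cluster 6, and -0.19 and -0.17 in cluster 3.

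The remaining lists had medians within the size rule in cycling-like cells: desmosome (0 of 8 past the rule, 0.09), tight and adherens junction (1 higher of 8, 0.19; Pvrl4 1.73), cornified envelope (0 of 5, 0.44) and stem cell markers (1 higher, 1 lower of 8, -0.27, with Ly6d 0.82 and Slc1a3 -0.62). So did transcription factors (0 of 13, 0.00), Notch (1 and 1 of 7, -0.12; Nrarp 1.62, Dll1 -1.45), EGF receptor (0 of 3, 0.37) and YAP (1 lower of 2, -0.20; Ajuba -0.85). Within it as well were Hedgehog (0 of 1, -0.27), immediate early (1 and 1 of 10, -0.17; Ier5 1.15, Junb -0.70), heat shock (1 and 1 of 11, -0.16; Hsp90aa1 1.01, Hspa1a -0.75), unfolded protein response (1 and 1 of 11, 0.13; Hsp90b1 0.83, Ddit3 -0.72) and p53 targets (1 higher of 7, 0.01; Cdkn1a 1.03). Glycolysis (2 lower of 12, -0.04; Aldoa -1.30, Pfkp -0.61), oxidative phosphorylation (1 higher of 72, 0.18; Ndufb7 0.63), ribosomal proteins (0 of 80, -0.30), interferon (1 lower of 8, 0.05; Ifitm3 -0.87) and clock (1 lower of 5, -0.28; Tef -1.94) completed them. By cluster, the cornified envelope list was past the rule in cluster 6 (1.02, 4 higher of 5) and at -0.42 on 2 genes in cluster 3, and the cyclin list was at 0.67 in S-like cells. Among matched random lists, the class medians lay at percentile 0 for hemidesmosomes and ribosomal proteins, 0.04 for Wnt, 0.78 for TGF-β and BMP, 98.8 for cyclins, 98.7 for oxidative phosphorylation and 99.9 for cholesterol synthesis. In all, 329 genes were higher and 104 lower of 4593 in 4244 cycling-like cells (median of all genes 0.00). The lower count was 171 without replicate 1 and 148 without replicate 2, where the rule rests on the remaining library alone. Taken apart, S-like cells had 363 higher and 116 lower of 4565, with the G1/S genes Ccne1 (3.76), E2f1 (3.40) and Cdk2 (2.18) in front. G2/M-like cells had 351 and 139 of 4589, with Cdkn2c at 2.57 and Ccnd2 at -2.28. The plot of list medians sets both comparisons side by side.

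**Figure D3:**
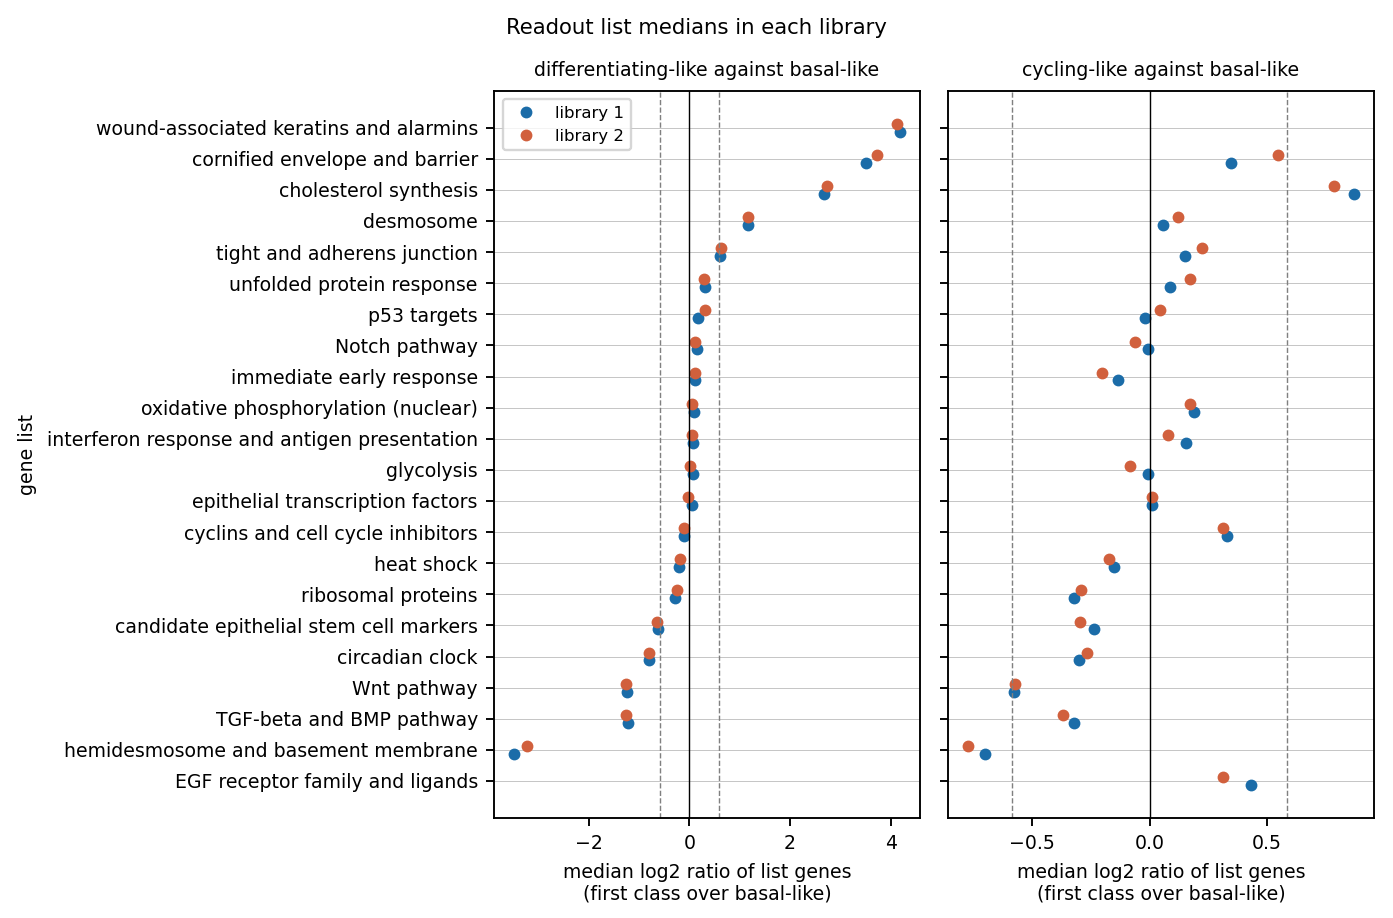
Median log2 ratio against basal-like cells of each readout list with at least 3 measured genes, for differentiating-like and cycling-like cells, with 1 point per library and dashed lines at 1.5-fold (0.58). The hemidesmosome list lies at -3.36 and -0.72, and the cornified envelope list at 3.62 and 0.44.

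The clusters that met the basal markers without a phase name were clusters 1 (3477 cells) and 13 (78), named basal-like, and clusters 8 (858) and 11 (150). The name was withheld from clusters 8 and 11 because of 1 leading gene each that was a marker of another list (Wfdc2 and Dcn). None of these clusters had a basal marker among its leading genes. The proliferation marker Mki67, a gene of the naming lists, stood at 112 CPM in cluster 8 against 9.16 in cluster 1. With cells thinned to 3000 UMIs, it was seen in 30.7% and 26.6% of cluster 8 against 2.53% and 2.42% of cluster 1. Langerhans-like cells had it in 0 of 8 and 16.0% of 25 cells. The shares in cluster 8 were near those of S-like cluster 7 (29.5% and 29.1%) and unnamed cluster 10 (33.8% and 27.7%). Between clusters 8 and 1, Top2a differed less (37.4 against 16.0 CPM). Thinned alike, Top2a was seen in 9.28% and 11.9% of cluster 8 against 59.0% and 61.8% of cluster 7. Over all kept cells, the G2/M markers had a median log2 of -0.13 in cluster 8 and -3.33 in cluster 1, and the S-phase markers of -0.89 and -0.57. Of 24 readout lists, 2 were apart in any of these clusters against the others pooled, interferon response and wound-associated genes. The number was 5 with a floor of 5 CPM and 1 at resolution 0.4 or under a 2-fold rule. It was 3 with readout genes allowed in clustering, with cells thinned, or with either replicate left out. The Hedgehog, YAP and EGF receptor lists had fewer than 3 measured genes and could not count, nor could the wound list in clusters 11 and 13. Cluster 13 was led by genes such as Cxcl10, Ifi44 and Gbp2, interferon-induced genes outside the list that were not kept out of clustering. Its interferon list is therefore not independent of how the cluster formed. All 15 measured interferon-response genes were higher in cluster 13 than in the other basal clusters (median log2 3.73). In front were the antiviral genes Ifit3 (51.9 against 0.2 CPM, log2 6.83 and 8.46, counting interval 6.48 to 9.70), Ifit1 (6.06; ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) and Isg15 (5.37). Cluster 11 was led by the fibroblast marker Dcn (6094 CPM against 118 in basal-like cells) and held Krt15 at 9465 against 2564. Of the readout genes it was set apart by Krt17, a keratin of appendages and wounds (2346 against 58.2 CPM, log2 5.33; ENSMUSG00000035557, chromosome 11, 100256217 to 100261029), with lower Klf5 (-1.63) and Ly6d (-1.44). Cluster 8 had the chaperone gene Hsp90b1 (681 against 237, log2 1.53), Cdkn1a (1.44) and Ovol1 (1.42) higher, and a wound list at -1.09 (1 higher, 2 lower of 3 genes). Cluster 1, against the other 3 pooled, had the interferon list at -0.83 (5 lower of 8) and the wound list at -0.63 (1 higher, 2 lower of 3). Taken against each cluster alone, its interferon list was at -0.47 (cluster 8), -0.80 (cluster 11, -0.50 in library 1) and -3.78 (cluster 13), and its wound list at 0.15, 0.02 and 0.27, so neither pooled wound median held between clusters 1 and 8. Krt17 stood at 58.6 CPM in cluster 1, 56.6 in cluster 8 and 39.0 in cluster 13.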

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

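Alternatives that left out cells by doublet score, or that widened the basal-like class, were chosen after seeing the data; the others were planned. Keeping doublet calls in, as planned, gave no value of its own, since none had been removed. No paired analysis was possible because there is 1 group. The cause was not tested for the differences below, except where the setting itself tests more or fewer genes or keeps more or fewer cells.

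Cells kept were 10035 under the stricter filter. Genes apart between the libraries numbered 20 with a floor of 5 CPM, 4 with a floor of 50 and 5 under the 2-fold rule. The non-keratinocyte share (1.33%) was 1.11% under the stricter filter, 1.503% at resolution 1.2 and 1.14% to 1.29% with each replicate left out. T/NK-like cells were not named with either library alone. The cycling-like share (27.8%) was 28.3% under the looser filter, 25.0% under the stricter and 26.0% at resolution 0.4 (where no S-like cluster formed). It was 27.4% with 4000 variable genes, 26.4% without high doublet scores, 34.2% from per-cell phase calls and 27.3% to 27.4% with each replicate left out. The differentiating-like share (22.6%) was 25.4% under the stricter filter, 20.6% at both resolutions, 26.9% with 4000 variable genes and 27.5% with readout genes allowed in clustering. Per-cell scores fix that share by construction and gave no value.

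Genes higher in differentiating-like cells (398) were 668 under median-of-ratios scaling, 663 and 214 with floors of 5 and 50, and 202 at 2-fold. Genes lower (851) were 429, 2239, 306 and 245 in that order, and 455 with 4000 variable genes. With 4000 variable genes, fewer genes were compared and the classes changed as well. Genes higher in cycling-like cells (329) were 703 and 158 with the floors and 123 at 2-fold. Genes lower (104) were 347, 44 and 10, 173 with 1000 variable genes, and 148 to 171 with each replicate left out. With a replicate left out, a gene had to pass 1.5-fold in the remaining library alone, which is an easier rule. Lists apart among basal clusters (2) were 1 at resolution 0.4, 5 with a floor of 5 and 1 at 2-fold. They were 3 with readout genes allowed in clustering, with cells thinned and with each replicate left out.

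Of 15 list medians past 1.5-fold, 236 of 238 alternative values had the same direction and 217 stayed past it. The exceptions in direction were stem cell markers in differentiating-like cells (0.0085 with a floor of 50) and the wound list in cycling-like cells (-0.0732 with cells thinned). Of 50 named genes past the rule, 699 of 700 values had the same direction and 697 stayed past it. Krt16 in differentiating-like cells was -0.57 with per-cell scores. Most of these genes were named because they lay furthest apart in the same cells. The values therefore do not show how well calls near the cutoff hold. Depth limits the classes of 8 to 25 cells per library. Genes set 1.5-fold apart, on the cutoff itself, were recovered in 18 of 48 and 10 of 50 simulated cases with counting noise only.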

Other observations

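All tests of explanations below were chosen after the pattern had been seen, and comparisons of single clusters were outside the plan.

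The largest cluster without a name, cluster 2 (2499 cells), held keratins of both sides and met the markers of neither (median log2 of the basal markers -0.32, of the differentiating markers -0.34). It carried Krt5 (2289 CPM against 3566 in basal-like cells), Trp63 (228 against 518), Krt14 (2455 against 9935) and Krt15 (848 against 2564) beside Krt13 (15358) and Krt4 (13432), and Itgb4 at 41.2. Against basal-like cells, 193 genes were higher and 126 lower of 4423. Hemidesmosome genes were lower in 8 of 9 (median log2 -1.53). Desmosome genes were higher in 7 of 9 (0.75), cornified envelope genes in 7 of 7 (1.51), cholesterol synthesis in 6 of 8 (1.57) and Notch genes in 3 of 6 (0.90; the receptor gene Notch3 at 3.49). The differentiation regulator Zfp750 (3.24) and the inhibitor Cdkn1a (2.54) were higher, and Lamb3 (-2.69) and Wnt10a (-2.63) lower. Of all compared genes, 3 were past 1.5-fold above both basal-like and differentiating-like cells (Thbd, Grip1 and Prlr), none of them in a readout list. Cluster 10 (483 cells) had 363 genes higher and 235 lower of 4444 than basal-like cells, with Zfp750 at 3.53, Cdkn1a at 2.88, Itga3 at -3.46 and Ccnd2 at -3.38. Unlike cluster 2, it was led by histone genes and by Ccnb2, Cdkn3 and Cenpa of mitosis, and it held Mki67 at 128 CPM against 9.13, with less Krt4 (6304). Its median doublet score was 0.0673, and no test of doublets was run for it.

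Cycling cells and differentiating cells were each divided too. Between the G2/M-like clusters, cluster 6 had 134 genes higher and 82 lower of 4632 than cluster 3, with hemidesmosome genes lower in 7 of 8 (median -1.22), cornified envelope genes higher in 5 of 5 (1.12), desmosome genes higher in 5 of 9 (0.63), Zfp750 at 3.19, Notch3 at 2.87 and Wnt10a at -2.14. Among differentiating-like clusters, cluster 5 led in cornified envelope genes (10 of 15 higher, 0.97; Scel 2.75), and cluster 4 was lowest in them (12 of 15 lower, -1.41). Cluster 9 had wound genes higher in 6 of 6 (median 5.01; the alarmins S100a8 6.47 and S100a9 6.56, Krt17 4.87) and interferon-response genes in 13 of 13 (2.79; Ifit1 5.19, Psmb8 4.28, B2m 2.79), with Lor at -2.01.

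Clusters 2 and 6 held Krt13 and Krt4 together with basal or cycling genes. Doublets are argued against for cluster 2 by median UMIs per cell at 0.373 of the sum of basal-like and differentiating-like medians, although its median doublet score (0.0652) was above those of cluster 1 (0.0395) and of the differentiating-like clusters (0.0382 to 0.0529). The smaller of the Krt13 and Krt4 levels was 9.46 (cluster 2) and 5.31 (cluster 6) times that of Langerhans-like cells, though T/NK-like cells held 6858 (Krt13) and 7269 CPM (Krt4, with 592 and 560 UMIs in 2 of the 26 cells); free RNA as the source of most of it is argued against by the median cell, with 57 Krt4 and 92 Krt13 UMIs in cluster 2 and 35 and 80 in cluster 6, against 7 and 14 in basal-like, 9 and 10 in Langerhans-like and 8 and 10.5 in T/NK-like cells. For cluster 6, the G2/M markers could not decide on doublets of a cluster 3 cell with a differentiating-like cell. They stood at 0.777 of cluster 3, too near the share of 0.710 and 0.706 that such a mixture needs. The rule set for this test needed both the G2/M markers and the median UMIs, so by that rule doublets stayed undecided. Taken alone, median UMIs of 0.508 and 0.505 of the partners' sum argue against such doublets as most of the cluster. So do its medians of 35 Krt4 and 80 Krt13 UMIs, against 249 to 572 and 226 to 474 in the differentiating-like clusters. Doublets in a part of cluster 6 are not excluded, since single cells reached 3008 Krt4 UMIs. Cluster 2 may therefore hold cells that pass from the basal to the differentiating state, which no group of the design could test.

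Differentiating-like cells held little Itgb4 although they came through a sort for its protein. A larger RNA content that dilutes the transcript is argued against, since Itgb4 UMIs per cell were 0.225 of the basal-like value. Hemidesmosome genes had a median of 0.249 of the basal-like UMIs per cell. This argues against droplets that also held a basal-like cell as most of the class. It cannot decide on such doublets in a part of the class, nor on pairs sorted together and separated before loading. A gate that let through cells low in CD104, and protein that outlasted its transcript, cannot be told apart for these 22.6% of keratinocytes, because no protein value was used here. No biological explanation was tested, as the design has 1 group.

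Cluster 9 stood out from the other differentiating-like clusters by wound and interferon genes. Genes outside the lists that led it, such as Sprr2a3, Chil4 and Alox15, were not kept out of clustering. Its list values are therefore not independent of how the cluster formed. A single library is argued against by shares of 4.05% and 4.51% of kept cells, 1.11-fold apart. Damaged cells cannot be told apart from intact ones by the median mitochondrial share of 3.07%, which lay between the 2.82% of cluster 5 and the 3.60% of cluster 4 after cells above 10% had been left out. Whether the cells came from 1 of the 10 pooled mice cannot be told apart from a state found in many, because no map from cells to mice was found in the sources used here. No biological explanation was tested, as the design has 1 group.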
